A study of Mus musculus with 12 samples.

How the data were processed

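RNA was measured by sequencing in 12 libraries of cultured mouse cells of the C57BL/6 strain, 3 from each of 4 groups: control OPCs, mutant OPCs, control OLs and mutant OLs. Control cells were Mettl14 fl/fl and mutant cells Mettl14 fl/fl with Olig2-Cre. Libraries had been made from 1 µg of total RNA with the Illumina TruSeq RNA kit, per the labels. The labels do not say whether libraries of the same replicate number came from the same animals or cultures, so each library was treated as a separate culture.

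The values used are raw counts of reads per gene, which the authors deposited as 1 table with no normalization. Whole numbers and column sums that differ between libraries show this unit. The authors' notes name FastQC 0.11.8, STAR 2.6.1, kallisto 0.44.0, Subread 1.6.3, R 3.5.1 and the genome build mm10. Which of these tools made the counts, the annotation release and the strand setting are not given in the sources used here. Without the strand setting, a gene that overlaps another on the opposite strand can hold reads of its neighbour, and genes with near-identical copies, such as ribosomal protein genes, can share reads. The table held 39056 genes, 13235 of them without a count. Gene IDs were matched to GENCODE M21 for symbols and positions; 184 did not match and held 0.0152% of counts. Mitochondrial genes held 2.03, 2.26, 2.14 and 2.42% of counts in control OPCs, mutant OPCs, control OLs and mutant OLs, and the 10 most abundant genes held 4.26, 4.40, 7.32 and 4.35%.

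Genes with enough counts were kept with filterByExpr by group (edgeR 4.0.16 in R 4.3.3), which left 16713. Libraries were scaled by TMM, and 1 quasi-likelihood model with a coefficient per group was fitted to all 12 libraries, so the 4 groups share an estimate of the spread. The common biological coefficient of variation was 0.0814. Tested were mutant against control in OPCs and in OLs, OLs against OPCs in control and in mutant cells, and the interaction, which is the difference between the genotype effects in OLs and in OPCs. All tests were two-sided. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. With 3 libraries against 3 an exact permutation test has 10 splits and cannot go below 0.1, which is why a model across genes was used. Levels are CPM with TMM-scaled library sizes, log2 fold changes are those of the model, and SE is approximate, the size of the log2 fold change divided by the square root of F. A fold change fitted against a group with at most 3 counts in total depends on the prior count, so for such genes CPM is given alone in the comparisons that use that group.

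Before the data were examined, the comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed. The 29 lists hold OPC identity genes, genes of committed and newly formed OLs, myelin and mature OL genes, oligodendrocyte transcription factors, inhibitors of differentiation, m6A machinery, axoglial adhesion and paranode, cholesterol synthesis, fatty acid and sphingolipid synthesis, mitosis, DNA replication, p53 targets, the integrated stress response, the unfolded protein response, immediate early genes, the interferon response, histone modifiers, splicing factors, Wnt targets, Notch and BMP targets and ribosomal proteins. They also hold markers of astrocytes, neurons, microglia, endothelium, mural cells and fibroblasts, Schwann cells and neural crest, and erythrocytes, and sex-linked genes. A list with at least 5 tested members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 28 lists of a comparison; the erythrocyte list had 1 tested member and no set test. Camera with an estimated correlation and fry were run beside it. Member counts are given over all genes tested and adjusted over the list alone.

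The rule names Mettl14 and Olig2. It names, for each comparison, the 6 genes with the largest rise and the 6 with the largest fall among genes that passed, reached 10 CPM in the higher group and had no overlap between the libraries of the groups; the interaction needed only the test and the level. Symbols of the form Gm plus digits or ending in Rik were left out. For each list described it names up to 4 members with the smallest p and up to 2 members of the highest level that did not pass. A list is described when its set test passed or when it is one of the OPC, committed, myelin, transcription factor, inhibitor, m6A or mitosis lists. From these genes the text gives a selection. Olig1, Mbp, Plp1 and Myrf were added after their values were seen, and so were the genes said to be so in the closing part.

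The alternatives were relative log expression, upper quartile and library size scaling, no filter, a filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, the 6 libraries of a comparison alone, an adjusted p under 0.01, a 2-fold threshold and leaving out each library in turn. A sex term, with libraries at 100 CPM or more of Xist coded female, was chosen after seeing the data. A sign change between settings where neither value passed was counted as the same result. The numbers of genes called at both stages or in both genotypes were set against the product of the list lengths over the genes tested.

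The model was tested on simulated data with the means and spread of these libraries. Of genes simulated to change, it recovered 82% at 1.5-fold and 96% at 2-fold in OPCs, 92 and 92% in OLs, 81.6 and 95.9% in control differentiation, 83.7 and 97.9% in mutant differentiation, and 64 and 82% in the interaction. Among unchanged genes, of which there were at least 15007 in each simulated set, it called 6, 18, 10, 8 and 9. These made 3.16, 8.65, 5.32, 4.35 and 5.23% of the calls, so in 3 of the 5 sets the share of wrong calls was above the 5% aimed at. Each simulated set changed 200 genes, a small part of those tested. In the real comparisons 51.4 to 81.6% of genes passed, so the simulation does not show how TMM scaling performs there. Between libraries of a group, chi-square per degree of freedom lay between 7.46 and 40.1, where counting error alone gives 1, so the 3 libraries per group limit the precision more than depth does. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Reads, splicing and m6A sites were not analysed here.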

Results

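The series measured mRNA in cultured mouse oligodendrocyte precursor cells (OPCs), the dividing progenitors of the oligodendrocyte lineage, and in oligodendrocytes (OLs), the cells that make myelin in the central nervous system. The precursors had been isolated from the brains of newborn mice by immunopanning, in which antibodies on a dish capture the wanted cells, and platelet-derived growth factor kept them dividing. OLs were obtained from such precursors by withdrawing the growth factor and giving thyroid hormone. Control cells carried loxP-flanked alleles of Mettl14 without Cre recombinase, and mutant cells carried the same alleles with Cre expressed from Olig2, a gene of the oligodendrocyte lineage. Each of the 4 groups held 3 libraries, 12 in all. Total counts per library lay between 51510341 and 57690524. Levels are given below as CPM, counts scaled to a common library size with TMM factors, as mean ± SD with n = 3 libraries per group. Of 39056 genes, 16713 had enough counts to be tested.

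Mettl14, which encodes a subunit of the RNA methyltransferase that writes N6-methyladenosine (m6A), lies on the minus strand of chromosome 3 from 123368297 to 123386108 in mm10. Its level was lower in every mutant library than in every control library. In OPCs it was 53.8 ± 1.86 CPM in controls and 23.8 ± 0.406 CPM in mutants (log2 fold change -1.17, SE 0.0542, edgeR adjusted p = 4.27e-09). In OLs it was 49.0 ± 1.41 CPM in controls and 16.9 ± 1.15 CPM in mutants (log2 fold change -1.54, SE 0.0553, edgeR adjusted p = 4.08e-11). The counts are per gene, so reads from exons outside the deleted part count toward the level that remained. The effect was larger in OLs by -0.36 log2 units (edgeR adjusted p = 0.00133), a difference that missed the threshold when libraries were scaled by size only (-0.16, adjusted p = 0.117; 0.000532 to 0.117 over the alternatives tried).

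Olig2, a transcription factor needed for the oligodendrocyte lineage and the gene that names the Cre driver, lies on chromosome 16 from 91225457 to 91228677. It was lower in all 6 mutant libraries than in the control libraries of the same stage. Its level was 818 ± 25.1 CPM in control and 461 ± 32.6 CPM in mutant OPCs (log2 fold change -0.83, SE 0.0564, edgeR adjusted p = 9.1e-08). In OLs it was 332 ± 12.1 CPM in controls and 208 ± 9.04 CPM in mutants (log2 fold change -0.68, edgeR adjusted p = 9.94e-08). The difference between the stages did not pass (0.15, edgeR adjusted p = 0.132), but it passed with DESeq2 (adjusted p = 0.0414), with scaling by library size only (0.35, adjusted p = 0.00293) and without mutant OPC replicate 3 (adjusted p = 0.0182). Over the alternatives tried its adjusted p lay between 0.00293 and 0.265. Its neighbour Olig1 was at 1485 ± 130 and 1620 ± 125 CPM in control and mutant OPCs and did not pass there, and in OLs it rose from 1206 ± 14 to 1793 ± 196 CPM.

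**Figure D1:**
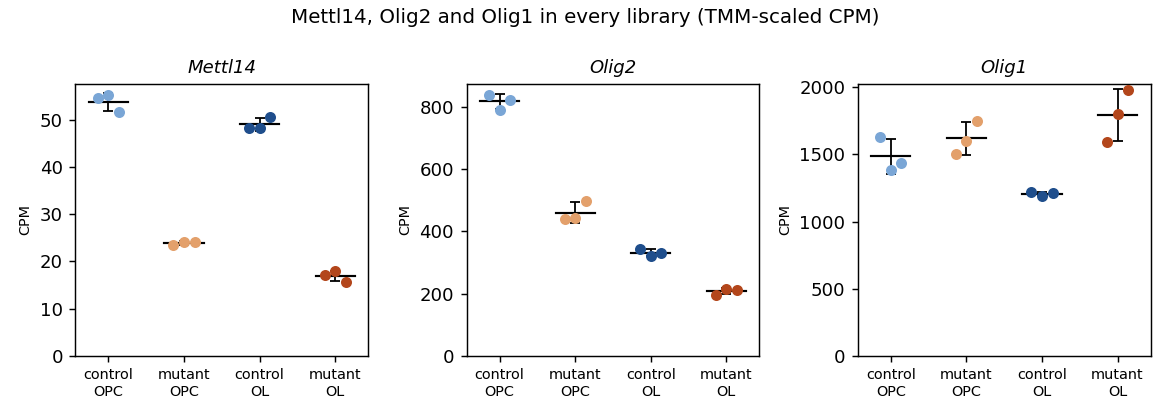
Level of Mettl14, Olig2 and Olig1 (CPM after TMM scaling, vertical axis) in every library of the 4 groups; points are libraries, bars are means and whiskers the SD over 3 libraries. Mettl14 averages 53.8 and 49.0 CPM in control OPCs and OLs against 23.8 and 16.9 CPM in the mutants, and Olig2 is lower in the mutants at both stages.

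The comparison of genotypes in OPCs asked how dividing precursors differ when Mettl14 is deleted. Genes of cell division were lower in mutant OPCs. Of 25 mitosis genes, 22 fell and 1 rose (median log2 fold change -0.45, camera adjusted p = 7.43e-06; adjusted p = 0.732 with an estimated correlation). Hmmr, a spindle protein, fell from 164 ± 3.94 to 98.3 ± 0.498 CPM. Plk1, a kinase of mitotic entry, fell from 167 ± 12.6 to 110 ± 4.34 CPM, and Ccnb1, which encodes cyclin B1, fell from 366 ± 9.84 to 244 ± 15.1 CPM. Mki67, a marker of cycling cells, was at 991 ± 20.5 and 985 ± 39.9 CPM and did not pass (edgeR adjusted p = 0.921). Of 26 DNA replication genes, 23 fell and 1 rose (median -0.40, camera adjusted p = 1.78e-05; adjusted p = 0.732 with an estimated correlation). Among them were the helicase subunits Mcm6, from 328 ± 7.17 to 217 ± 7.11 CPM, and Mcm5, from 305 ± 5.61 to 204 ± 6.91 CPM, and the primase subunit Prim1, from 90.3 ± 0.651 to 60.7 ± 2.09 CPM. Ribosomal protein genes were lower for 16 of 27 and higher for 0 (median -0.17, camera adjusted p = 0.00371; adjusted p = 0.769 with an estimated correlation), with Rpl4 falling from 1172 ± 17.9 to 903 ± 69.7 CPM. Of 30 splicing factor genes, 16 fell and 2 rose (median -0.15, camera adjusted p = 0.0119; adjusted p = 0.732 with an estimated correlation). Celf2 fell from 250 ± 6.02 to 160 ± 11.5 CPM and Rbfox2 rose from 128 ± 3.14 to 157 ± 10.4 CPM. Adjusted over the list alone, 22 mitosis, 23 DNA replication, 17 ribosomal and 17 splicing genes fell, and 1, 2, 0 and 2 rose.

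Genes downstream of Notch and bone morphogenetic protein (BMP) signalling were higher in mutant OPCs, with 10 of 18 rising and 2 falling (camera adjusted p = 0.00892; adjusted p = 0.732 with an estimated correlation). Their median log2 fold change was 1.14 as fitted and 0.56 with members that had a group at 0 counts set to their bound. Id3 and Id1, inhibitors of basic helix-loop-helix factors, rose from 10.5 ± 1.49 to 82.7 ± 18.5 CPM and from 1.19 ± 0.393 to 8.27 ± 2.35 CPM. The receptor gene Notch3 rose from 3.46 ± 0.408 to 32.4 ± 9.67 CPM and Atoh8 from 0.810 ± 0.353 to 8.80 ± 3.15 CPM. Astrocyte marker genes moved the same way, with 12 of 20 rising and 2 falling (median 0.60, camera adjusted p = 0.0454; adjusted p = 0.732 with an estimated correlation). The water channel gene Aqp4 rose from 2.40 ± 0.605 to 9.86 ± 1.16 CPM, Mlc1 from 2.81 ± 1.27 to 19.7 ± 4.22 CPM and the glutamate transporter gene Slc1a2 from 43.2 ± 3.10 to 97.0 ± 17.1 CPM. The astrocyte list missed the threshold without mutant OPC replicate 3 (camera adjusted p = 0.0893; 0.0172 to 0.0893 over the alternatives of scaling, block, sex term and libraries). The counts for both lists were the same when adjusted over the list alone.

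The lists of the oligodendrocyte lineage had members moving both ways in OPCs, and none of their set tests passed. Of 24 OPC identity genes, 4 rose and 9 fell (median -0.05, camera adjusted p = 0.351). The Notch ligand gene Dll3 fell from 61.7 ± 7.82 to 13.1 ± 4.44 CPM and Rlbp1 from 175 ± 6.46 to 61.1 ± 12.1 CPM. Of 24 genes of committed and newly formed OLs, 9 rose and 5 fell (camera adjusted p = 0.68). Tns3 rose from 178 ± 6.03 to 317 ± 39.2 CPM and Gpr17, a receptor of committed precursors, fell from 1004 ± 132 to 280 ± 131 CPM. Gpr17 overlaps Lims2, a gene of much lower level. Of 50 myelin genes, 18 rose and 8 fell (median 0.25, camera adjusted p = 0.351). Ttyh2 rose from 3.89 ± 0.429 to 23.8 ± 3.18 CPM and Opalin from 0.431 ± 0.131 to 3.38 ± 1.2 CPM, Cmtm5 fell from 28.4 ± 0.448 to 13.3 ± 0.622 CPM, and Cldn11 was at 268 ± 20.8 and 238 ± 53 CPM without passing, but fell without mutant OPC replicate 3 (-0.37, edgeR adjusted p = 0.00174; 0.00174 to 0.714 over the alternatives). Of 25 oligodendrocyte transcription factor genes, 9 rose and 5 fell (camera adjusted p = 0.696); Zeb2 rose from 240 ± 6.97 to 359 ± 10.2 CPM, and Sox10, at 712 ± 73.4 and 690 ± 45.4 CPM, did not pass. Of 25 inhibitors of differentiation, 13 rose and 7 fell (median 0.29, camera adjusted p = 0.276), among them Daam2, up from 1.69 ± 0.238 to 12.4 ± 2.79 CPM, and Sox11, up from 256 ± 4.96 to 486 ± 55.7 CPM. Of 25 tested genes of the m6A machinery, Mettl14 among them, 12 rose and 7 fell (median 0.12, camera adjusted p = 0.484). The m6A reader gene Ythdf2 rose from 134 ± 4.37 to 287 ± 37.1 CPM and Rbm15, a partner of the writer complex, from 50.5 ± 0.785 to 106 ± 13.6 CPM. When adjusted over the list alone, 7 committed genes fell, and the other counts of these 6 lists were the same. Mutant OPC replicate 3 stood apart from the other 2 mutant OPC libraries in these groups, with 21 of 24 committed genes and 38 of 50 myelin genes above them, by medians of 0.45 and 0.31 log2 units.

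Across all genes, 9150 of 16713 passed in OPCs, 4700 higher and 4450 lower in mutants, and 1757 of them changed at least 2-fold (1193 higher, 564 lower). The libraries of the groups did not overlap for 9880 genes, 59.1% of those tested against 10% by chance. Among genes that reached 10 CPM, Igfbp5, a binding protein of insulin-like growth factors, rose most, from 1.89 ± 0.192 to 56.4 ± 23.7 CPM (log2 fold change 4.89, SE 0.293, edgeR adjusted p = 3.29e-08). C1qtnf1 (4.70), Lrtm2 (4.67), the receptor tyrosine kinase-like gene Ror1 (4.21), Pdzrn3 (4.01) and the adhesion gene Cntn6 (4.0) followed on the log2 scale. Xist fell most, from 801 ± 668 to 0.648 ± 0.166 CPM (edgeR adjusted p = 0.00281; adjusted p = 0.161 with voom and 2.34e-08 with DESeq2). This transcript of the inactive X chromosome was at 1092, 1275 and 36.7 CPM in control OPC replicates 1, 2 and 3, at 670 CPM in control OL replicate 3 and at most 1.10 CPM in the other 8 libraries, so the sexes were not balanced between genotypes. Fam19a4 (-2.56), Dll3 (-2.24), the retinoic acid receptor gene Rarb (-2.18), Mgll, a lipase of endocannabinoid breakdown (-1.98), and Slitrk1 (-1.96) fell next most. Rarb overlaps Top2b and is uncertain, because the strand setting of the counting is not given in the sources used here.

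The other fixed lists had no set test that passed in OPCs, although the unfolded protein response passed without control OPC replicate 1 (camera adjusted p = 0.0207 against 0.0769) and with a sex term (0.0324; 0.0207 to 0.129 over the alternatives). Among lists of cell function, the numbers higher and lower were 10 and 7 of 26 for axoglial adhesion, 6 and 2 of 26 for cholesterol synthesis, 6 and 4 of 26 for fatty acid and sphingolipid synthesis, and 4 and 9 of 26 for p53 targets. They were 3 and 8 of 24 for the integrated stress response, 2 and 11 of 20 for the unfolded protein response, 5 and 4 of 22 for immediate early genes, 6 and 6 of 23 for the interferon response, 15 and 8 of 28 for histone modifiers and 6 and 4 of 13 for Wnt targets. Among markers of other cells, 7 and 9 of 21 neuron, 1 and 0 of 7 microglia, 5 and 0 of 11 endothelial, 6 and 2 of 19 mural and fibroblast and 0 and 4 of 12 Schwann and neural crest genes passed, with 0 and 1 of 5 sex-linked genes. Of 9 erythrocyte genes 1 had enough counts, and it did not pass in OPCs. Adjusted over the list alone, 3 cholesterol, 4 immediate early and 16 histone modifier genes rose, 12 unfolded protein, 2 immediate early, 9 histone modifier and 1 mural genes fell, and the other counts were the same.

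The comparison of genotypes in OLs asked how cells cultured under differentiating conditions differ when Mettl14 is deleted. Myelin genes were lower almost throughout. Of 50 myelin and mature OL genes, 49 fell and 0 rose (median log2 fold change -3.02, camera adjusted p = 4.11e-13; adjusted p = 0.425 with an estimated correlation). The galactosylceramide synthase gene Ugt8a fell from 1287 ± 104 to 194 ± 16.2 CPM, the carbonic anhydrase gene Car2 from 328 ± 34.7 to 32.8 ± 4.26 CPM, the receptor gene Gpr37 from 269 ± 33.3 to 32.2 ± 2.82 CPM and Qdpr from 416 ± 32.1 to 89.7 ± 2.98 CPM. Gjc3 was the member that did not pass, at 566 ± 46.1 and 534 ± 4.78 CPM. Mbp and Plp1, which encode the main proteins of central myelin, and Myrf, a transcription factor of myelin genes, were picked for plotting after their values were seen. Mbp fell from 11150 ± 1966 to 888 ± 218 CPM, Plp1 from 21650 ± 2506 to 1868 ± 343 CPM and Myrf from 807 ± 62.9 to 104 ± 14.6 CPM.

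**Figure D2:**
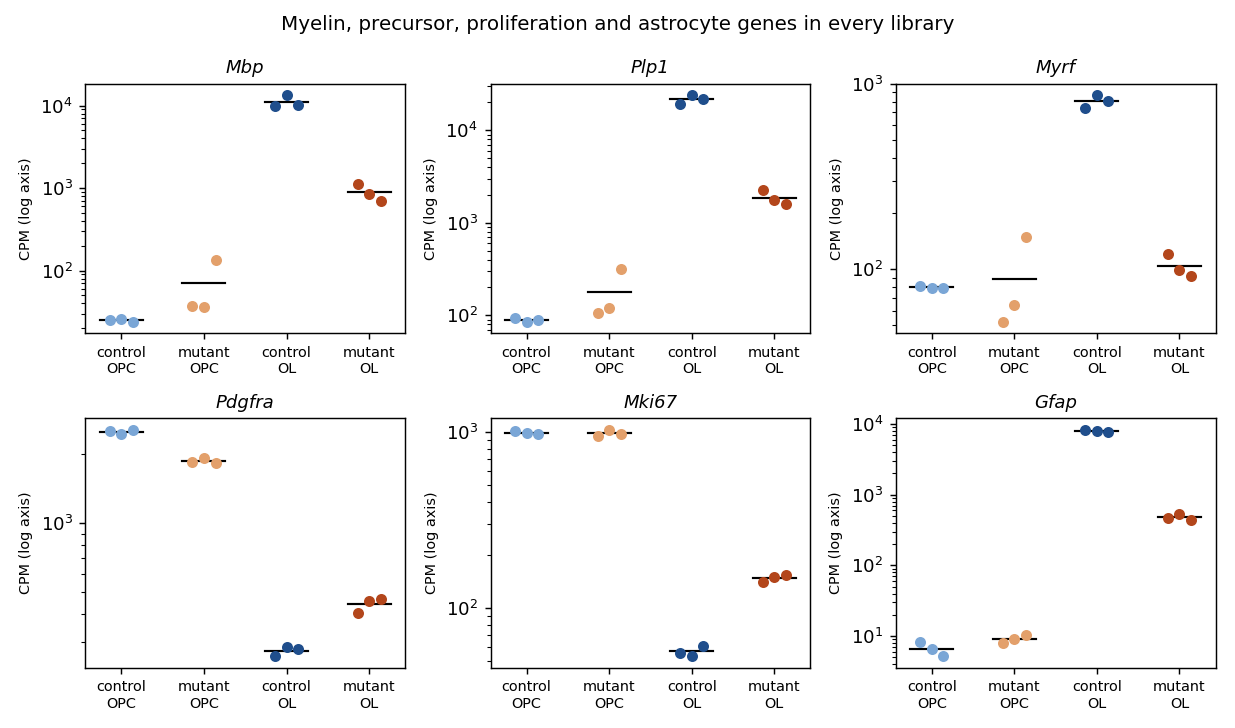
Level of 6 genes (CPM after TMM scaling, vertical log axis) in every library of the 4 groups; points are libraries and bars are means over 3 libraries. In control OLs Mbp, Plp1 and Myrf average 11150, 21650 and 807 CPM against 888, 1868 and 104 CPM in mutant OLs, while Pdgfra and Mki67 are higher in mutant than in control OLs and Gfap is lower.

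Genes of committed and newly formed OLs were also lower in mutant OLs, with 22 of 24 falling and 1 rising (median -1.73, camera adjusted p = 6.34e-06; adjusted p = 0.425 with an estimated correlation). Chn2 fell from 204 ± 13.1 to 25.0 ± 1.23 CPM, Rras2 from 76.5 ± 4.88 to 9.49 ± 0.973 CPM and Pik3r3 from 564 ± 29.2 to 178 ± 11.2 CPM. Of 25 transcription factor genes of the lineage, 18 fell and 6 rose (median -0.62, camera adjusted p = 0.0398; adjusted p = 0.425 with an estimated correlation). Nkx6-2 fell from 138 ± 8.88 to 13.7 ± 2.67 CPM and the thyroid hormone receptor gene Thra from 428 ± 2.78 to 184 ± 12.9 CPM, while the chromatin remodeller gene Chd7 rose from 64.9 ± 2.65 to 118 ± 9.01 CPM. Nkx6-2 overlaps Inpp5a and is uncertain. Of 26 genes of fatty acid and sphingolipid synthesis, 19 fell and 2 rose (median -0.54, camera adjusted p = 0.000862; adjusted p = 0.425 with an estimated correlation). The list shares Ugt8a, Fa2h and Gal3st1 with the myelin list. The transcription factor list shares Myrf with the myelin list, and the axoglial list given next shares Mag, Omg and Gjc2. The falls of these lists are therefore not fully separate from that of the myelin list. The ceramide synthase gene Cers2, which overlaps Setdb1, fell from 467 ± 41.1 to 156 ± 2.02 CPM. Fasn, which encodes fatty acid synthase, was at 774 ± 45.1 and 699 ± 48.0 CPM without passing, though it passed when mutant OPC replicate 3 was left out of the fit. Of 26 genes of axoglial adhesion and the paranode, 19 fell and 6 rose (median -0.45, camera adjusted p = 0.0467; adjusted p = 0.517 with an estimated correlation). Dlg1 fell from 317 ± 16.7 to 90.8 ± 2.06 CPM and Dag1, which encodes dystroglycan, rose from 497 ± 19.3 to 1562 ± 74.1 CPM. The axoglial call was lost without control OL replicate 2 (camera adjusted p = 0.0629) and without mutant OL replicate 1, 2 or 3 (0.0523, 0.0514 and 0.0531), and with the replicate block (0.0544). Over the alternatives it lay between 0.0381 and 0.0629. These 5 lists had the same counts when adjusted over the list alone.

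Genes of division, protein synthesis and inhibition of differentiation were higher in mutant OLs. Of 25 mitosis genes, 22 rose and 0 fell (median 0.50, camera adjusted p = 0.000115; adjusted p = 0.517 with an estimated correlation). Mki67 rose from 56.7 ± 4.15 to 149 ± 7.05 CPM and the centromere protein gene Cenpf from 24.2 ± 1.99 to 76.7 ± 4.79 CPM. Of 26 DNA replication genes, 16 rose and 4 fell (median 0.21, camera adjusted p = 0.0467; adjusted p = 0.665 with an estimated correlation), with Ccne1, which encodes cyclin E1, rising from 8.29 ± 0.742 to 18 ± 1.52 CPM. Ribosomal protein genes rose for 20 of 27 and fell for 0 (median 0.33, camera adjusted p = 0.000862; adjusted p = 0.608 with an estimated correlation), among them Rplp0, from 418 ± 13.7 to 620 ± 2.03 CPM. Of 25 inhibitors of differentiation, 16 rose and 7 fell (median 0.61, camera adjusted p = 0.0467; adjusted p = 0.425 with an estimated correlation). Sox11 rose from 44.9 ± 2.91 to 160 ± 4.66 CPM and Notch1 from 148 ± 7.63 to 357 ± 13.7 CPM. Of 13 Wnt target genes, 9 rose and 3 fell (median 0.86, camera adjusted p = 0.0467; adjusted p = 0.425 with an estimated correlation), with Apcdd1 rising from 63.5 ± 5.44 to 169 ± 13.9 CPM and Axin2 from 24.5 ± 2.08 to 38.4 ± 0.626 CPM. Apcdd1 and Axin2 are also in the inhibitor list, which shares Pdgfra, Cspg4, Ptprz1 and Sox6 with the OPC identity list. The rises of the Wnt and inhibitor lists are therefore not fully separate. Of 26 p53 target genes, 17 rose and 5 fell (median 0.45, camera adjusted p = 0.0459; adjusted p = 0.608 with an estimated correlation). Eda2r rose from 23.9 ± 3.31 to 75.2 ± 5.39 CPM and Plk3 fell from 86.2 ± 11.2 to 12.8 ± 2.46 CPM. The replicate block ended the calls for inhibitors (camera adjusted p = 0.0564), DNA replication (0.0564), p53 targets (0.051) and Wnt targets (0.0564). Scaling by library size only ended the calls for inhibitors (camera adjusted p = 0.129), p53 targets (0.0544) and Wnt targets (0.0964). The calls were also lost without control OL replicate 1 for inhibitors (0.0501), without control OL replicate 2 for Wnt (0.0629) and DNA replication (0.0987), and without mutant OL replicate 3 for DNA replication (0.11). Over the alternatives the adjusted p lay between 0.0436 and 0.129 for inhibitors, 0.0317 and 0.0544 for p53, 0.0358 and 0.0964 for Wnt and 0.0212 and 0.11 for DNA replication. Counts of these 6 lists did not differ when adjusted over the list alone.

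Marker genes of other neural cells were lower in mutant OLs. Of 20 astrocyte genes, 14 fell and 4 rose (median -0.75, camera adjusted p = 0.0398; adjusted p = 0.425 with an estimated correlation). Gfap, an intermediate filament gene of astrocytes, fell from 8019 ± 329 to 480 ± 43.0 CPM and the glutamine synthetase gene Glul from 2251 ± 145 to 933 ± 29.5 CPM, while Hepacam, at 366 ± 6.60 and 364 ± 11.1 CPM, did not pass and was higher with scaling by library size only (0.18, edgeR adjusted p = 0.00624; 0.00624 to 0.975 over the alternatives). Of 21 tested neuron genes, 12 fell and 4 rose (median -0.65, camera adjusted p = 0.0467; adjusted p = 0.425 with an estimated correlation), with Elavl3, an RNA-binding protein gene, falling from 434 ± 32.3 to 62.6 ± 5.27 CPM. The neuron call was lost without control OL replicate 3 (0.0577) without mutant OL replicate 3 (0.0539) and with the replicate block (0.051), with a range of 0.0197 to 0.0577 over the alternatives. OPC identity genes rose for 13 and fell for 8 of 24 without a set test that passed (median 0.42, camera adjusted p = 0.204). Cspg5 rose from 233 ± 3.59 to 789 ± 9.08 CPM and Sox6 from 151 ± 6.10 to 317 ± 11.7 CPM, and the endothelin receptor gene Ednrb fell from 883 ± 15 to 401 ± 30.4 CPM. Of the 25 m6A machinery genes, 13 rose and 9 fell (median 0.17, camera adjusted p = 0.278). Ythdf2 rose from 74.3 ± 2.10 to 194 ± 12.8 CPM and Rbm15 from 29.2 ± 1.68 to 89.7 ± 5.08 CPM. For these 4 lists the counts were the same when adjusted over the list alone.

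Across all genes, 12139 passed in OLs, 5975 higher and 6164 lower in mutants, and 4274 changed at least 2-fold (2159 higher, 2115 lower). With scaling by library size only, 62.2% of calls were higher against 49.2% with TMM, as this scaling moved the median of all genes by 0.19 log2 units. The libraries of the groups did not overlap for 12911 genes, against 10% by chance. Among genes that reached 10 CPM, Zfp819 was at 14.1 ± 1.90 CPM in mutants against 0.0130 ± 0.0113 CPM in controls. Mroh2a (8.05 on the log2 scale), the zinc finger gene Zfp988 (7.76), the transglutaminase gene Tgm7 (6.84, and 7.62 without control OL replicate 3), Mpz, the main protein gene of peripheral myelin (6.69), and Zfp981 (6.33) followed. Mpz rose from 0.346 ± 0.109 to 36.2 ± 3.58 CPM (SE 0.225, edgeR adjusted p = 2.57e-11). Among genes without overlap between the libraries of the groups, the largest falls were in Ppp1r14a (-5.54), the secretogranin gene Scg2 (-5.03), Aspa, an enzyme of N-acetylaspartate breakdown (-4.66), Ceacam20 (-4.51), the phosphodiesterase gene Pde8a (-4.44) and Gdnf, a neurotrophic factor gene (-4.40). Xist, outside that limit, fell by more (-7.76, edgeR adjusted p = 0.00629), a call lost without control OL replicate 3 (0.28, edgeR adjusted p = 0.905). Aspa fell from 36.8 ± 4.25 to 1.46 ± 0.281 CPM (SE 0.196, edgeR adjusted p = 1.38e-10).

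The remaining lists had no set test that passed in OLs, although Schwann and neural crest markers passed without mutant OL replicate 3 (camera adjusted p = 0.0487 against 0.104; 0.0487 to 0.178 over the alternatives) and histone modifiers with a sex term (0.0463; 0.0457 to 0.0732). The numbers higher and lower were 7 and 6 of 26 for cholesterol synthesis, 8 and 12 of 24 for the integrated stress response and 5 and 8 of 20 for the unfolded protein response, whose medians turned positive with scaling by library size only, and 12 and 4 of 22 for immediate early genes and 10 and 6 of 23 for the interferon response. They were 15 and 9 of 28 for histone modifiers, 15 and 5 of 30 for splicing factors and 6 and 11 of 18 for Notch and BMP targets. Among markers of other cells they were 2 and 2 of 7 for microglia, 4 and 0 of 11 for endothelium, 8 and 5 of 19 for mural cells and fibroblasts, 6 and 2 of 12 for Schwann cells and neural crest and 0 and 1 of 5 for sex-linked genes, and the 1 erythrocyte gene rose. Adjusted over the list alone, 5 cholesterol and 14 splicing genes rose, and the other counts were the same.

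**Figure D3:**
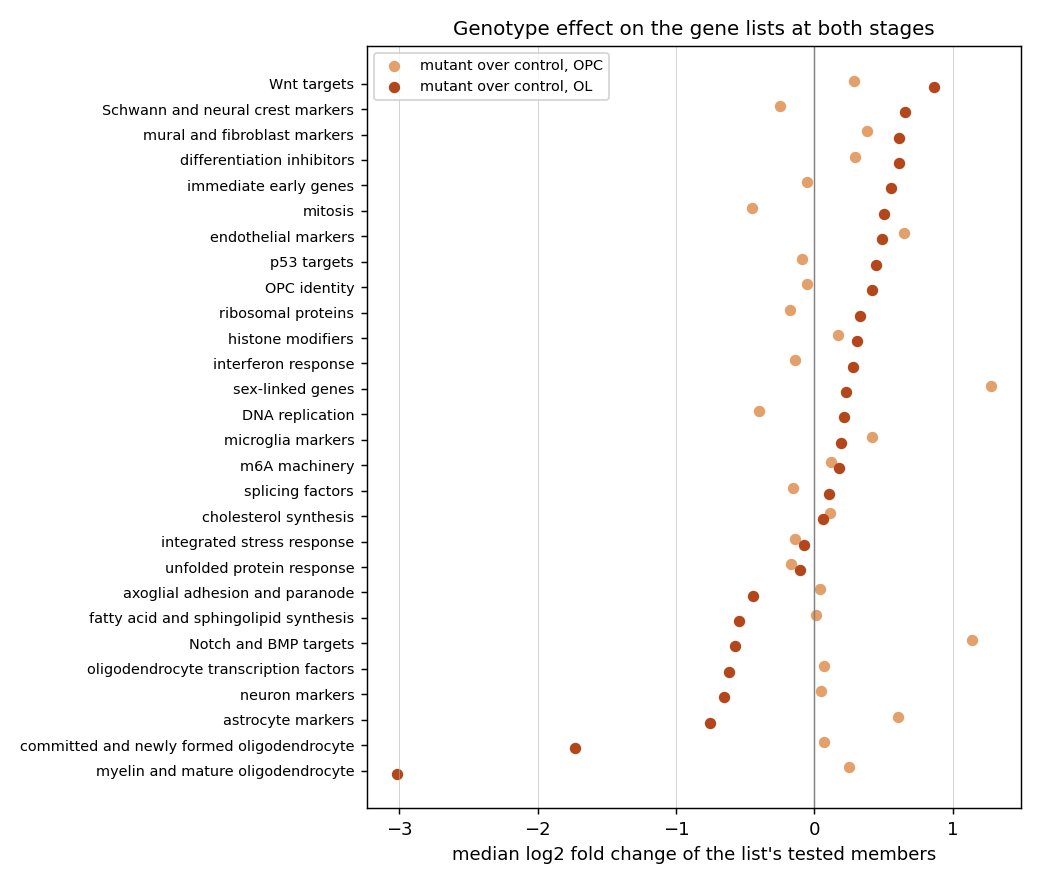
Median log2 fold change of mutant over control for the tested members of 28 gene lists (horizontal axis), in OPCs (light points) and OLs (dark points). Myelin genes lie at 0.25 in OPCs and -3.02 in OLs, and mitosis genes at -0.45 and 0.50; the Notch and BMP point in OPCs, 1.14, is 0.56 with members at 0 counts set to their bound.

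Differentiation in control cells was compared as the reference for the mutant. Of the 50 myelin genes, 49 rose and 1 fell (median log2 fold change 5.44, camera adjusted p = 1.88e-13; adjusted p = 0.22 with an estimated correlation). Mal, a lipid raft protein gene of myelin, rose from 0.576 ± 0.152 to 1254 ± 127 CPM and Cryab, a small heat shock protein gene, from 0.344 ± 0.112 to 272 ± 15.1 CPM. Committed OL genes rose for 21 and fell for 3 of 24 (median 2.24, camera adjusted p = 0.000252; adjusted p = 0.429 with an estimated correlation). Axoglial genes rose and fell for 21 and 3 of 26 (1.18, camera adjusted p = 0.000438; adjusted p = 0.224 with an estimated correlation), and fatty acid and sphingolipid genes for 20 and 5 of 26 (1.40, camera adjusted p = 0.00128; adjusted p = 0.256 with an estimated correlation). Astrocyte genes rose for 19 and fell for 1 of 20 (median 4.81, camera adjusted p = 2.61e-07; adjusted p = 0.0507 with an estimated correlation), with Gfap rising from 6.63 ± 1.55 to 8019 ± 329 CPM and Aqp4 from 2.40 ± 0.605 to 2103 ± 133 CPM. Notch and BMP targets rose for 14 of 18 and fell for 2 (2.82, camera adjusted p = 0.00102; adjusted p = 0.22 with an estimated correlation), interferon genes for 17 and 3 of 23 (1.42, camera adjusted p = 0.0121; adjusted p = 0.148 with an estimated correlation), and mural and fibroblast genes for 14 and 1 of 19 (2.59, camera adjusted p = 0.0131; adjusted p = 0.224 with an estimated correlation).

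Mitosis and DNA replication genes fell on control differentiation in 25 of 25 and 26 of 26 (medians -3.63 and -3.07, camera adjusted p = 2.11e-12 and 5.09e-12; adjusted p = 0.224 and 0.22 with an estimated correlation). Mki67 fell from 991 ± 20.5 to 56.7 ± 4.15 CPM. Ribosomal genes fell in 27 of 27 (-1.52, camera adjusted p = 7.77e-11; adjusted p = 0.256 with an estimated correlation). Splicing factor genes fell in 25 of 30 with 4 higher (-1.05, camera adjusted p = 5.39e-06; adjusted p = 0.235 with an estimated correlation). Histone modifier genes fell in 24 of 28 with 3 higher (-0.81, camera adjusted p = 8.4e-05; adjusted p = 0.148 with an estimated correlation) and m6A machinery genes in 22 of 25 with 1 higher (-0.61, camera adjusted p = 7.69e-05; adjusted p = 0.148 with an estimated correlation). The m6A reader gene Igf2bp2 fell from 98.3 ± 5.71 to 14.9 ± 1.21 CPM, and Ezh2, the methyltransferase of Polycomb repression, from 190 ± 4.27 to 49.6 ± 1.82 CPM. OPC identity genes fell for 15 and rose for 8 of 24 without a set test that passed (median -0.81, camera adjusted p = 0.0679); Pdgfra, the receptor gene for the growth factor withdrawn, fell from 2517 ± 52.5 to 276 ± 13.9 CPM. Transcription factor genes rose for 12 and fell for 12 of 25 (median -0.11, mean 1.2, camera adjusted p = 0.989), and inhibitors rose for 10 and fell for 12 of 25 (median -0.27, mean 0.18, camera adjusted p = 0.678). In control differentiation 14 of the 28 tested lists passed, and the counts given here were the same when adjusted over the list alone.

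In control cells 13639 genes passed, 6994 higher and 6645 lower in OLs, and 7058 changed at least 2-fold (4222 higher, 2836 lower). The libraries did not overlap for 14047 genes, against 10% by chance. The largest rises among genes that reached 10 CPM started from levels near 0. Ceacam20 and Ddo went from 0 counts in the OPC libraries to 15.2 ± 3.90 and 13.2 ± 0.793 CPM, Glycam1 from 0.00630 ± 0.0109 to 51.2 ± 7.92 CPM, the zinc transporter gene Slc39a12 from 0.0185 ± 0.000403 to 106 ± 6.95 CPM, and the protease gene Klk6 from 0.0251 ± 0.0289 to 107 ± 9.53 CPM. The log2 fold change was 11.95 for Klk6, and 13.19 without control OPC replicate 3, and 11.09 for Mal. The largest falls were in the amino acid transporter gene Slc38a4 (-7.17), the chromatin protein gene Hmga2 (-6.76), Col19a1 (-6.50), Cd93 (-6.49), Pnlip (-6.47) and the laminin gene Lama1 (-5.57). Mettl14 fell by 0.13 log2 units (edgeR adjusted p = 0.0305), a call lost with DESeq2 (0.0556), with relative log expression scaling (0.0503), with a sex term (0.0856) and without control OPC replicate 1 or 2 or control OL replicate 1 or 2 (0.0924, 0.0953, 0.0916 and 0.092); over the alternatives tried the adjusted p lay between 0.000421 and 0.0953.

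Differentiation in mutant cells was compared in the same way. Of 50 myelin genes, 44 rose and 3 fell (median log2 fold change 2.46, camera adjusted p = 3.7e-08; adjusted p = 0.295 with an estimated correlation). Mal rose from 0.936 ± 0.165 to 136 ± 29.4 CPM and Cryab from 1.10 ± 0.0814 to 136 ± 13.6 CPM, and Myrf, at 88.4 ± 52.5 and 104 ± 14.6 CPM, did not pass (edgeR adjusted p = 0.44). That missing call rests on 1 library: without mutant OPC replicate 3 Myrf rose by 0.83 log2 units (adjusted p = 1.85e-06; 1.85e-06 to 0.899 over the alternatives). Committed OL genes rose for 9 and fell for 8 of 24 (median -0.03, mean 0.35, camera adjusted p = 0.887), and Gpr17, at 280 ± 131 and 232 ± 34.0 CPM, did not pass. Axoglial genes rose for 17 and fell for 7 of 26 (median 0.80, camera adjusted p = 0.0269; adjusted p = 0.415 with an estimated correlation). Astrocyte genes rose for 19 of 20 and fell for 0 (camera adjusted p = 1.11e-07) and interferon genes for 20 of 23 with 1 lower (median 2.13, camera adjusted p = 5.13e-05), and both calls held with an estimated correlation (adjusted p = 0.0215 each). The astrocyte median was 3.92 as fitted and 3.30 with members at 0 counts set to their bound. The interferon-induced gene Ifit3 rose from 0.555 ± 0.0854 to 9.26 ± 0.887 CPM. Schwann and neural crest genes rose for 10 and fell for 1 of 12 (median 1.98, camera adjusted p = 0.0134; adjusted p = 0.217 with an estimated correlation), among them Mpz, from 0.116 ± 0.0842 to 36.2 ± 3.58 CPM, Cdh19, from 2.84 ± 0.281 to 49.6 ± 0.590 CPM, and Prx, from 5.20 ± 0.194 to 19.4 ± 1.75 CPM. Notch and BMP targets rose for 14 of 18 and fell for 3 (1.17, camera adjusted p = 0.0213; adjusted p = 0.295 with an estimated correlation), and mural and fibroblast genes for 15 and 1 of 19 (1.88, camera adjusted p = 0.0015; adjusted p = 0.204 with an estimated correlation).

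Genes of division also fell when mutant cells differentiated. Mitosis genes fell in 25 of 25 and DNA replication genes in 26 of 26 (medians -2.69 and -2.46, camera adjusted p = 1.59e-11 for both; adjusted p = 0.247 and 0.217 with an estimated correlation), with Mki67 falling from 985 ± 39.9 to 149 ± 7.05 CPM. Ribosomal genes fell in 27 of 27 (-1.09, camera adjusted p = 1.81e-09; adjusted p = 0.297 with an estimated correlation). Splicing factor genes fell in 26 of 30 with 4 higher (-0.78, camera adjusted p = 1.03e-05; adjusted p = 0.279 with an estimated correlation). Histone modifier genes fell in 18 of 28 with 6 higher (-0.37, camera adjusted p = 0.0213; adjusted p = 0.279 with an estimated correlation) and m6A machinery genes in 23 of 25 with 1 higher (-0.46, camera adjusted p = 8.79e-05; adjusted p = 0.204 with an estimated correlation). OPC identity genes fell for 14 and rose for 7 of 24 (camera adjusted p = 0.237), with Pdgfra falling from 1872 ± 44.0 to 442 ± 33.8 CPM. Transcription factor genes rose for 8 and fell for 14 of 25 (median -0.20, mean 0.20, camera adjusted p = 0.341) and inhibitors rose for 10 and fell for 12 of 25 (0.678). Fatty acid and sphingolipid genes rose for 17 and fell for 6 of 26 without passing as a set (camera adjusted p = 0.0811; 0.0439 without mutant OPC replicate 3, and 0.0439 to 0.106 over the alternatives). In mutant differentiation 13 of the 28 tested lists passed, and the counts given here were the same when adjusted over the list alone. In mutant cells 13173 genes passed, 6512 higher and 6661 lower in OLs, and 5987 changed at least 2-fold (3754 higher, 2233 lower). The libraries did not overlap for 13305 genes, against 10% by chance. From levels near 0, Defb1 reached 15.1 ± 0.608 CPM, Sfrp5 71.0 ± 13.7 CPM, Spta1 14.4 ± 0.910 CPM and Cfi 16.8 ± 1.19 CPM. The complement gene C3 rose from 0.261 ± 0.0909 to 559 ± 21.3 CPM and Lcn2 from 0.0680 ± 0.0278 to 101 ± 9.92 CPM. Cd93 (-6.35), Hmga2 (-6.06), Gsx1 (-5.48), Htr1b (-5.39), Pcna-ps2 (-5.10) and Nptx2 (-4.64) fell most on the log2 scale. Pcna-ps2 is a pseudogene that can share reads with Pcna and is uncertain.

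The interaction asked whether the effect of genotype differed between OPCs and OLs, and it passed for 8591 genes, 3996 with a more positive and 4595 with a more negative effect in OLs. Of these, 2832 differed at least 2-fold (1104 and 1728). With scaling by library size only, 65.3% of calls were positive against 46.5% with TMM, as this scaling moved the median of all genes by 0.20 log2 units. Of 28 tested lists, 16 passed, and 0 of the 28 passed with an estimated correlation. Myelin genes were more negative in OLs for 47 of 50 and more positive for 0 (median -3.02, camera adjusted p = 6.07e-18; adjusted p = 0.291 with an estimated correlation), and mitosis genes more positive for 25 of 25 (median 0.92, camera adjusted p = 1.8e-11; adjusted p = 0.291 with an estimated correlation). Opalin had a log2 interaction of -7.17 (SE 0.382, edgeR adjusted p = 5.16e-09), after a rise in mutant OPCs and a fall in mutant OLs from 58.8 ± 11 to 3.17 ± 0.754 CPM. Nkx6-2 (-7.06), Enpp6 (-6.87, and -5.48 without mutant OPC replicate 3), Tgfbi (-6.71, and -7.31 without control OPC replicate 2) and St18 (-6.45, and -5.42 without mutant OPC replicate 3) followed. Mroh2a (6.57), Mpz (6.26, and 5.64 without control OPC replicate 2), the proprotein convertase gene Pcsk5 (4.56) and the imprinted transcript H19 (3.84, and 5.06 without mutant OPC replicate 3) were the most positive with a fold that could be given. Zfp819, Sfrp5 and Ceacam20 also passed but had at most 3 counts in a group. The call for Sfrp5 (edgeR adjusted p = 0.0342) was lost with voom and without control OPC replicate 2 or 3 or mutant OPC replicate 1 or 3 (0.105, 0.224, 0.0596 and 0.0728; 0.000901 to 0.224 over the alternatives). The call for Ceacam20 (0.0184) was lost without mutant OPC replicate 3 (adjusted p = 1; 1.21e-05 to 1 over the alternatives).

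Effects of genotype at the 2 stages, which share no library, overlapped in direction. Higher in mutants at both stages were 3100 genes, against 1680 for independent lists of the same lengths, and lower at both were 2898, against 1641. Genes higher in mutant OPCs and lower in mutant OLs numbered 859, against 1733, and the reverse 633, against 1591. Fold changes correlated across genes, which are not independent replicates, with Pearson's r = 0.381 and Spearman's rho = 0.425. Differentiation effects in control and mutant cells, which also share no library, were both higher for 5191 genes (2725 for independent lists), both lower for 5283 (2648) and opposite for 621 and 387, with r = 0.831 across genes. The slope of mutant on control fold changes over genes called in controls was 0.685, against 0.957 in simulated counts with no interaction. Of the 4222 genes that rose at least 2-fold in controls, 2005 rose less in mutants by the interaction test and 328 rose more, and of the 2836 that fell at least 2-fold, 1506 fell less and 121 fell more; simulated counts with no interaction gave 0 in each case.

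**Figure D4:**
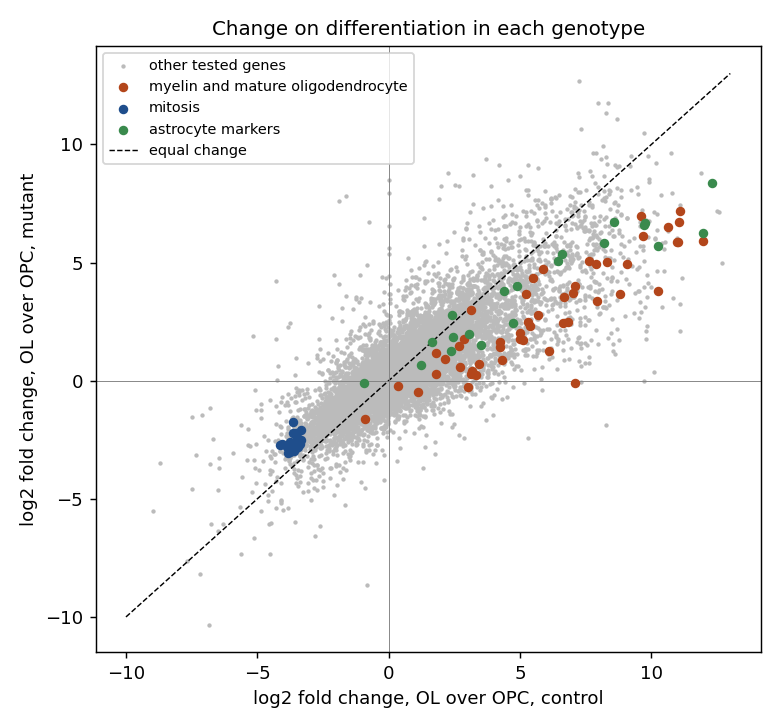
Log2 fold change of OLs over OPCs in mutant cells (vertical axis) against that in control cells (horizontal axis) for each of the 16713 tested genes, with myelin, mitosis and astrocyte genes coloured and the dashed line marking equal change. Myelin genes have medians of 5.44 in controls and 2.46 in mutants and lie mostly under the line; mitosis genes have medians of -3.63 and -2.69.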

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

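The tests of explanations for Olig2, for the astrocyte genes and for mutant OPC replicate 3 were chosen only after the results were seen, while the counts over other splits of the libraries were set before their values were seen.

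The effect of genotype differed between OPCs and OLs, by the interaction test, for 8591 genes and 16 lists, and with an estimated correlation none of the 16 passed. Lists with a more negative effect in OLs had median interactions, on the log2 scale, of -3.02 for myelin (camera adjusted p = 6.07e-18), -1.96 for committed and newly formed OLs (4.49e-07), -1.29 for astrocyte markers (6.33e-05), -0.51 for fatty acid and sphingolipid synthesis (0.000542), -0.54 for axoglial adhesion (0.0144), -1.94 for Notch and BMP targets (0.0189), -0.49 for transcription factors (0.0189) and -0.87 for neuron markers (0.0457). Lists with a more positive effect were mitosis (0.92, camera adjusted p = 1.8e-11), ribosomal proteins (0.48, 2.08e-08), DNA replication (0.60, 1.59e-07), p53 targets (0.47, 0.00247), splicing factors (0.18, 0.00379), Schwann and neural crest markers (1.24, 0.0148), OPC identity (0.37, 0.0156) and histone modifiers (0.19, 0.0189); the adjusted p with an estimated correlation lay between 0.183 and 0.352 for the 16 lists. The neuron call was lost without control OPC replicate 2 or 3 (0.062 and 0.0533), mutant OPC replicate 1 or 3 (0.0513 and 0.0627), control OL replicate 1 or 3 (0.0567 and 0.0667) or mutant OL replicate 3 (0.0884), with a range of 0.00987 to 0.0884 over the alternatives. The Schwann call was lost with scaling by library size only (0.0593; 0.00455 to 0.0593 over the alternatives). Members more positive and more negative numbered 12 and 3 of 24 for OPC identity, 1 and 19 of 24 for committed OLs and 4 and 14 of 25 for transcription factors. They numbered 1 and 15 of 20 for astrocyte markers, 2 and 16 of 26 for fatty acid and sphingolipid synthesis, 4 and 15 of 26 for axoglial adhesion, 3 and 10 of 18 for Notch and BMP targets and 4 and 11 of 21 for neuron markers. The numbers were 27 and 0 of 27 for ribosomal proteins, 22 and 0 of 26 for DNA replication, 16 and 4 of 26 for p53 targets, 15 and 2 of 30 for splicing factors, 7 and 1 of 12 for Schwann markers and 13 and 3 of 28 for histone modifiers. Adjusted over the list alone, 48 myelin, 17 fatty acid, 18 axoglial, 11 Notch and BMP, 14 neuron and 4 OPC identity genes were more negative and 23 DNA replication, 18 p53, 14 histone modifier and 2 astrocyte genes more positive, and the other counts were the same.

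Of 156 genes that the naming rule gives for the 2 genotype comparisons, 128 had an interaction that passed, and 33 passed in opposite directions at the 2 stages. Given here are the genes named in the text that passed, with log2 interactions in brackets, leaving out those with at most 3 counts in a group. Genes higher in mutant OPCs and lower in mutant OLs were Opalin (-7.17), Nkx6-2 (-7.06), Enpp6 (-6.87), Tgfbi (-6.71), St18 (-6.45), Mbp (-5.13), Pde8a (-4.95), Id1 (-4.92), Plp1 (-4.54), Gfap (-4.52), Id3 (-4.29), Gpr37 (-3.41), Aqp4 (-3.10), Elavl3 (-3.06), Ttyh2 (-2.81), Cryab (-2.66), Pik3r3 (-2.13), Glul (-2.01), Cers2 (-1.79), Tns3 (-1.79), Zeb2 (-1.17) and Igf2bp2 (-0.83). Lower in mutant OPCs and higher in mutant OLs were Pcsk5 (4.56), Pnlip (3.21), Cdh19 (2.22), Eda2r (1.92), Hmmr (1.15), Pdgfra (1.11), Plk1 (0.92), Mcm6 (0.89), Mcm5 (0.77) and Ccnb1 (0.74). Higher in mutants at both stages, with a larger rise in OLs, were Mroh2a (6.57), Hspg2 (3.07), Mmp2 (2.77), Tgm7 (2.31), Lama1 (1.49), Cenpf (1.39), Rbfox2 (0.95), Sox6 (0.94), Sox11 (0.91), Dag1 (0.91), Col27a1 (0.89), Notch1 (0.80), Apcdd1 (0.71), Rbm15 (0.55), Tead1 (0.46), Axin2 (0.35) and Ythdf2 (0.29), and with a smaller rise in OLs were C1qtnf1 (-3.86), Lrtm2 (-3.33), Mlc1 (-2.35), Lamb2 (-1.97), Yap1 (-1.80), Daam2 (-1.79), Ror1 (-1.24), Tead2 (-1.16), Wwtr1 (-1.07), Notch3 (-0.98), Slc1a2 (-0.87) and Cntn6 (-0.85). Lower at both stages, with a larger fall in OLs, were Rras2 (-2.66), Dlg1 (-1.56), Cmtm5 (-0.61), Mettl14 (-0.36) and Ednrb (-0.30), and with a smaller fall in OLs were Slitrk1 (0.94) and Rlbp1 (0.41). Genes that passed in OLs and not in OPCs were Klk6 (-6.05), Scg2 (-5.71), Ppp1r14a (-4.82), Mal (-3.91), Gdnf (-3.75), Car2 (-3.27), Chn2 (-3.15), Myrf (-3.10), Sirt2 (-3.09), Ugt8a (-2.82), Cldn11 (-2.71), Plk3 (-2.70), Qdpr (-2.16), Nptx2 (-1.90), Gsx1 (-1.46), Thra (-1.24), Atp1b2 (-0.56) and Alkbh5 (-0.27), which were lower in mutants, and Mpz (6.26), H19 (3.84), Prx (3.18), C3 (2.39), Col19a1 (1.87), Cspg5 (1.63), Mki67 (1.40), Chd7 (0.99), Ccne1 (0.94), Rplp0 (0.60), Itgav (0.47) and Olig1 (0.45), which were higher. Genes that passed in OPCs and not in OLs were Igfbp5 (-4.78), Pdzrn3 (-4.35), Atoh8 (-3.24), Htr1b (-1.55) and Gjc3 (-1.08), which were higher in mutants, and Celf2 (0.61) and Rpl4 (0.38), which were lower. Nkx6-2 and Cers2 overlap other genes and are uncertain. Leaving out 1 library moved these interactions by over 1.5-fold. Without mutant OPC replicate 3 they were -5.48 for Enpp6, -5.42 for St18, -4.22 for Mbp, -3.86 for Plp1, -2.69 for Gdnf, -2.50 for Myrf and 5.06 for H19. Without control OPC replicate 2 they were -7.31 for Tgfbi and 5.64 for Mpz, without control OPC replicate 3 -7.29 for Klk6 and -4.39 for Gdnf, without control OPC replicate 1 -5.45 for Klk6, and without control OL replicate 3 3.09 for Tgm7. The interaction call was lost without at least 1 of the libraries for Rlbp1, Tead2, Ednrb, Ythdf2, Ror1, Wwtr1 and Tgm7. So was the OPC call of Cers2, Elavl3, Sox6, Pde8a, Igf2bp2, Gfap and Eda2r and the OL call of Ttyh2, Ccnb1, Mcm5, Slc1a2, Mlc1 and Alkbh5. Of genes placed as passing in OLs alone, Klk6, Scg2, Mal, Gdnf, Chn2, Myrf, Sirt2, Cldn11, Nptx2, Atp1b2, Alkbh5, H19, C3, Cspg5, Chd7 and Ccne1 passed in OPCs without at least 1 library, and Pdzrn3, placed as passing in OPCs alone, passed in OLs. Myrf and H19 fell in mutant OPCs without mutant OPC replicate 3 (-0.46 and -0.48).

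Splitting the libraries in other ways tested the numbers of genes called. For each comparison of 2 groups, 1 of 10 splits, the real one, gave as many genes, and the splits are too few for a share under 0.05. The real and highest other numbers were 9150 and 0 for genotype in OPCs, 12139 and 1 for genotype in OLs, 13639 and 0 for control differentiation and 13173 and 0 for mutant differentiation. Each other split mixes the groups compared, which moves their difference into the spread. Low numbers in those splits are thus set in advance and do not measure what chance gives. For the interaction, 100 of 200 splits of genotype within stage were drawn, and 3 of the 100, the real one included, gave at least the real 8591 genes. That share is under 0.05. Splits that mix the genotypes within a stage also move the genotype effects into the spread. Such splits can call few genes whether or not there is an interaction, so the share does not decide whether chance gives the interaction count. The highest other split, with 11742 genes, exchanged the genotypes of all 3 OL libraries and none in OPCs, which turns the test into one of the sum of the genotype effects. The next, with 8659 genes, exchanged 1 OPC and 3 OL libraries. Exchanging all OL libraries thus counts effects of genotype, whether the stages share them or not. Why the split with 8659 genes called as many was not tested.

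Olig2 was lower in mutants at both stages. Scaling between libraries is argued against, since over 4 scalings and both stages its weakest log2 change was -0.48. Fewer lineage cells in the mutant cultures are argued against by Olig1 and Sox10, of which the largest fall at either stage was -0.23. In mutant OLs Olig1 rose by 0.57 log2 units, so it does not count cells there. The argument in OLs rests on Sox10 alone. Mutant levels were 0.563 of the control level in OPCs and 0.625 in OLs. The loss of 1 Olig2 allele in the Cre driver line may explain both, and so may lowering of Olig2 by loss of Mettl14. Loss of 1 allele, with the output of the other unchanged, would give a larger fall than was seen at either stage. Lowering by loss of Mettl14 would give a larger fall of Olig2 where less Mettl14 was left. That was not seen either: Mettl14 fell more in OLs (-1.54 against -1.17) and Olig2 less (-0.68 against -0.83). The difference for Olig2 did not pass (edgeR adjusted p = 0.132). These explanations cannot be told apart, because every mutant library carries both the driver and the deletion. The way the driver line was made is not given in the sources used here. The driver and the deletion also go together in every other difference between the genotypes. The driver without the deletion was not among the samples, so an effect of lower Olig2 or of Cre stays open and untested.

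Gfap fell by 4.06 on the log2 scale in mutant OLs, with 14 of 20 astrocyte markers lower. Scaling is argued against, since the weakest change of Gfap over 4 scalings was -3.87. Fewer astrocytes would lower other astrocyte genes about as much. Of the 11 other members that rise at least 16-fold in control differentiation, the median change was -0.82 (SD 1.65) against -4.06 for Gfap, which argues against fewer astrocytes as the cause of the whole fall of Gfap. This test replaced an earlier one after its values had been seen. The earlier test argued against fewer astrocytes for the whole list when at least 2 of these members were higher. The present one rests on a threshold of 1 SD between the median and Gfap; at 2 SD it would not have excluded that cause. Fewer astrocytes may still explain the smaller falls: 9 of the 11 were lower, among them Aqp4 (2103 to 1006 CPM), and 2 were higher, Slc1a2 (0.30) and Mlc1 (0.45). Both lost the call when single OL libraries were left out but stayed higher, at 0.23 to 0.28 for Slc1a2 and 0.41 to 0.48 for Mlc1 where the call was lost. Gjb6, the lowest of these members in level, fell more than Gfap (-5.75, from 9.34 to 0.172 CPM). That can go with fewer astrocytes or with lower expression within the cells. The cultures started from immunopanned precursors, with Gfap at 6.63 CPM and Aqp4 at 2.40 CPM in control OPCs, which leaves little room for astrocytes at the start; their number in the OL cultures was not measured. Lower expression within the cells, with a change of -4.06 for Gfap, cannot be told apart from it for these members, because bulk counts do not separate cells.

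Mutant OPC replicate 3 stood apart from mutant OPC replicates 1 and 2, with Mbp at 135 CPM against 37.5 and 36.6, Enpp6 at 80.5 against 13.9 and 13.5, and H19 at 675 against 102 and 168; Mbp, H19, Yap1 and Tead2 were picked after their values were seen. Cells with intact Mettl14 in this library are argued against, since its Mettl14 level gives 0.872% of control RNA (spread 6.19%), while the 675 genes with a genotype effect of at least 2-fold would need a median of 30.7%. More cells on the way to OLs may explain the rise of committed genes, 21 of 24 above the other libraries, and of myelin genes, 38 of 50 above. Across genes, which are not independent replicates, the deviation had a correlation of -0.0428 with the control differentiation effect and of -0.227 with the genotype effect in OPCs. The latter effect is computed with the same libraries, and no value for an unchanged library was computed, so it does not show on which side the library lay. Single genes went both ways: Yap1 (10.7 CPM against 26.9 and 24.5) and Tead2 (10.7 against 32.2 and 28.1) lay nearer to controls, and Mbp, Enpp6 and H19 further from them. Of mitosis genes, 20 of 25 were below the other libraries, by a median of -0.08 log2 units, which goes with more such cells, while 16 of 24 OPC identity genes were above, by a median of 0.23 log2 units. That more cells were on the way to OLs stays open, since none of these values decides it and the labels give no detail that sets the library apart.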

How the results depend on the processing

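The sex term was chosen only after the data were seen; the other alternatives were planned. Numbers of genes past the threshold stayed within 1.5 times the numbers reported under all alternatives of scaling, filter, tool, block, sex term and libraries, and under an adjusted p of 0.01. With the filter of at least 5 CPM the correlation of the differentiation effects was 0.874 against 0.831; the cause was not tested. Adding a 2-fold threshold left 1757 genes for genotype in OPCs, 4274 in OLs, 7058 and 5987 for control and mutant differentiation, 2832 for the interaction, and overlaps of 938 (genotype) and 4625 (differentiation), fewer by construction.

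A replicate block gave 9075, 12080, 13595, 13143 and 8480 genes in the order used above, and 7 of the 13 lists in OLs, as inhibitors (0.0564), axoglial (0.0544), DNA replication (0.0564), p53 (0.051), Wnt (0.0564) and neuron genes (0.051) missed the threshold. The replicate numbers gave no clear pairing: 18 correlations between libraries of the same number lay between -0.579 and 0.148, and 1 was above 0.1. Of the 18, 10 had their best match in their own number, more than chance gives with 3 libraries to match. These held all control OPC libraries against mutant OPCs and against mutant OLs, but no control OPC library against control OLs. Ddx3y, a gene of the Y chromosome, was at 2.59, 0.0186 and 64.4 CPM in control OPC replicates 1, 2 and 3. In control OL replicates 1, 2 and 3 it was at 128, 140 and 0.302 CPM. This argues against the same animals behind control OPC and control OL libraries of the same number. With a sex term the numbers were 7613, 11802, 13369, 13086 and 8154, and the unfolded protein response in OPCs (camera adjusted p = 0.0324) and histone modifiers in OLs (0.0463) passed in addition.

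Of gene values, 471 of 482 kept their direction and side of the threshold with relative log expression (1 weaker, 10 stronger), 445 with library size only (1 weaker, 30 stronger, 6 reversed), 468 of 481 with DESeq2, 474 of 482 with voom, 478 with the block, 476 with the sex term and 360 of 372 with the 6 libraries alone. The 6 reversals, with library size only, were Hnrnpa2b1 (0.17), Fto (0.125) and Hepacam (0.185) in OLs, Alkbh5 (-0.146) and Itgav (-0.148) in control differentiation and Hepacam in the interaction (0.194), close to the shift that this scaling gives to all genes, 0.194, -0.149 and 0.198.

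Leaving out libraries kept 3473 of 3546 gene values (9 weaker, 61 stronger, 3 reversed) and 980 of 1008 list results (18 weaker, 10 stronger). The 3 reversed in OPCs without mutant OPC replicate 3, where the log2 change was -0.215 for Tnr, -0.258 for Sirt2 and -0.182 for Atp1b2; their leave-one-out values reached 0.293, 0.356 and 0.095. The cause was not tested. Ranges over libraries left out were 8150 to 9557 genes in OPCs, 11587 to 11717 in OLs, 13295 to 13456 and 12657 to 13182 in control and mutant differentiation and 7905 to 8953 for the interaction. Mettl14 lay between -1.20 and -1.16 in OPCs and -1.58 and -1.48 in OLs, and Olig2 between -0.89 and -0.80 and between -0.70 and -0.64. Overlaps lay between 5433 and 6349 (genotype, 5998 reported) and 10141 and 10577 (differentiation, 10474 reported), r between 0.352 and 0.399 and between 0.823 and 0.832, and the slope between 0.67 and 0.693. Lists called numbered 5 to 7, 10 to 13, 14, 13 to 15 and 15 to 16.

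List results were the most dependent on the test. Camera with an estimated correlation called 0, 0, 0, 2 and 0 lists against 6, 13, 14, 13 and 16, as it allows members to move together by their measured correlation. Fry, which does not compare a list with other genes, called 18, 26, 24, 23 and 20. With library size only 136 of 140 list results were kept, with the sex term 138 and with the block 133. Folds of genes with few counts are imprecise also above 3 counts in a group: Mpz, Klk6 and Tgm7 moved by over 1.5-fold when 1 library was left out.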

Other observations

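The sets below, and the genes named with them, were picked after the data were seen; the test of exon length was written before its values per library were seen but after a correlation over fold changes had been.

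With exonic length, GC content and level held fixed, genes with longer exons had more positive changes in mutants. A candidate explanation is that long exons mark transcripts that lose m6A when Mettl14 is deleted; m6A itself was not measured. Over 11115 genes, the rank correlation of the longest exon with the change of a library against controls, so adjusted, lay between 0.188 and 0.203 in mutant OPCs and between 0.077 and 0.086 in mutant OLs. In control libraries against the other controls it lay between -0.054 and 0.035. Without that adjustment it lay between 0.134 and 0.185 in mutants and between -0.255 and 0.197 in controls, so the unadjusted values do not separate the genotypes. The adjusted values fit the explanation in being positive and above all controls, found and tested on the same data. They were smaller in mutant OLs, where Mettl14 fell more, but a correlation does not give the size of a change. Without the adjustment, genes whose longest exon had at most 1036 bp had median log2 changes of -0.095 in OPCs and -0.129 in OLs. Those with at least 3706 bp had medians of 0.129 and 0.170. Whether the effect rises with the loss of Mettl14 is therefore not decided. Mutant libraries of a stage were set against the same controls and are not independent values. Other features that go with exon length stay untested.

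Of 11 sets tried after seeing the data, the YAP and TEAD pathway was picked because its members were seen to rise. In OPCs 10 of 12 members were higher and 1 lower (median 1.87, camera adjusted p = 0.000331 over the 11 sets), and in OLs 10 and 1 (median 1.30, camera adjusted p = 0.00358); with an estimated correlation the adjusted p was 0.281 and 0.332. Yap1 rose from 1.95 ± 0.294 to 20.7 ± 8.75 CPM in OPCs and from 45.7 ± 1.09 to 140 ± 4.15 CPM in OLs, Wwtr1 from 3.52 ± 0.158 to 16.5 ± 7.49 and from 68.0 ± 5.06 to 152 ± 5.32 CPM, Tead1 from 76.2 ± 3.62 to 125 ± 15 and from 76.0 ± 4.74 to 171 ± 3.82 CPM and Tead2 from 1.63 ± 0.263 to 23.7 ± 11.4 and from 5.28 ± 0.599 to 34.4 ± 2.16 CPM. In OPCs the rise was smaller in mutant OPC replicate 3, at 10.7 CPM for Yap1 against 26.9 and 24.5 and 10.7 for Tead2 against 32.2 and 28.1. Also picked after their values were seen were Lamb2, from 0.810 ± 0.359 to 12.3 ± 5.85 and from 51.7 ± 4.17 to 199 ± 9.06 CPM, Col27a1 from 10.2 ± 0.0931 to 58.4 ± 6.03 and from 66.8 ± 10.5 to 707 ± 54.4 CPM, Mmp2 from 11.8 ± 0.749 to 49.0 ± 16.5 and from 2.94 ± 0.877 to 83.3 ± 10.9 CPM, and Hspg2 from 13.5 ± 1.02 to 145 ± 3.16 CPM in OLs; they were not tested as a set.

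With an estimated correlation none of the other 10 sets passed in either genotype comparison or in the interaction. Zinc finger genes named Zfp were higher for 168 and lower for 51 of 347 in OPCs (camera adjusted p = 0.000106; adjusted p = 0.332 with an estimated correlation) and for 228 and 52 in OLs (2.74e-08; 0.23). Histone genes, picked only by symbols that begin with Hist and a digit, were lower for 28 of 41 in OLs and higher for 0 (median -1.32, camera adjusted p = 0.000243, and 0.23 with an estimated correlation). In OPCs they were lower for 6 and higher for 3 (camera adjusted p = 0.518). In control differentiation the same set was higher for 33 and lower for 0 (median 2.39), while DNA replication genes fell. The set holds members of very different level, such as Hist1h1c at 157 CPM and Hist1h4d at 0.265 CPM in control OLs. How fully the libraries capture histone transcripts was not examined. The rise of these counts is therefore not read as a rise of all histone RNA, and its cause was not tested. Collagens were higher for 17 and lower for 6 of 41 in OPCs (camera adjusted p = 0.0348; adjusted p = 0.281 with an estimated correlation) and 22 and 11 in OLs (0.0393; 0.306). Laminins were higher and lower for 7 and 1 of 10 in OPCs (0.0406; 0.281) and 7 and 2 in OLs (0.066; 0.23), and complement and acute phase genes for 3 and 0 of 7 (0.0587; 0.281) and 5 and 0 (0.0393; 0.23). Ribosomal genes named Rps or Rpl were higher for 8 and lower for 39 of 93 in OPCs (camera adjusted p = 0.000927; adjusted p = 0.529 with an estimated correlation) and 68 and 6 in OLs (6.21e-06; 0.372). Genes with the longest exons, picked by a length limit, were higher for 1693 and lower for 993 of 4278 in OPCs (camera adjusted p = 0.0106; adjusted p = 0.281 with an estimated correlation) and 1947 and 1444 in OLs (0.0403; 0.335). Solute carriers (0.409 and 0.324), Hox genes (0.615 and 0.475) and ion channels (0.409 and 0.995) did not pass in OPCs or OLs.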
